A study of Mus musculus with 6 samples.

How the data were processed

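Sorted Mac1 and c-kit bone marrow cells of 12-month-old mice, mixed in equal parts, had been run on the 10x droplet platform with 3.1 chemistry that reads the 3-prime end of transcripts and counts unique molecular identifiers (UMIs). The labels put 6 libraries into 3 genotypes, WT, LysM-CRL and LysM-CRS, with 2 replicates each. The deposited matrices hold whole UMI counts per gene and cell barcode, not normalized, made with Cell Ranger 6.0.1 for WT and LysM-CRL and 6.1.1 for LysM-CRS, per the file headers. The submitters' processing notes name Cell Ranger 3.0.0, Seurat 4.3.0 and the GRCm38/mm10 build, and the step at which each was used is not given in the sources used here. The WT and LysM-CRL files end with the added features FLAG-CRL and tdtomato, and the LysM-CRS files with FLAG-CRL-tdtomato and FLAG-CRS-tdtomato. Whether intronic reads were counted is not given in the sources used here. The barcodes deposited numbered 10427, 11008, 10683, 10207, 10451 and 9320 for replicates 1 and 2 of WT, LysM-CRL and LysM-CRS, the smallest with 500 UMIs. Names and positions of 32158 of 32285 mouse genes (99.6%) were taken by gene ID from GENCODE mouse release 21, which uses GRCm38. The added features entered no test across genes.

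Cells with at least 300 genes and under 10% mitochondrial UMIs were kept. Doublets were scored per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.8% per 1000 cells, and cells with a score of 0.25 or more, 2.90% to 5.41% per library, were left out. This left 9529, 10225, 10121, 9725, 9525 and 8642 cells in the same order, 57767 of 62096 barcodes. Counts were scaled to 10000 per cell and log-transformed, the 2000 most variable genes were reduced to 30 principal components, and the graph of 20 shared neighbours was clustered with Leiden at resolution 1. Clustering was run within each processing batch, WT with LysM-CRL and LysM-CRS apart. Large clusters of mixed markers were divided again, from 200 cells up and at resolution 0.5. Names of the form X-like came from markers of 18 cell types, fixed before the data were examined. A name needed 3 detected markers, a mean marker score of at least 0.8 and a median of at least 1000 UMIs. Among the top 10 genes, markers of another type could not outnumber its own, nor tie with them at 3 or more. A cluster with none of its own markers there could therefore be named. The immature neutrophil-like cluster led by Spc25 and Top2a, 42.0% and 37.7% of that class in WT 1 and 2, was such a cluster. Of 73 clusters 15 stayed unnamed. Several of these choices were made after the clusters had been seen and before any test between genotypes. Clustering all libraries together, with and without scaling per library, and a Harmony-type correction were tried first, and batches were then clustered apart because the LysM-CRS cells separated from the others. The doublet threshold was fixed because the automatic one failed in 2 libraries, and the floor of 1000 median UMIs, the second round of clustering, the rule on ties and the minimum score, raised in steps, were set in the same way.

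For each of 5 classes with at least 20 cells in every library, raw counts were summed per library, because libraries and not cells are the replicates. The smallest of these classes in cells was monocyte-like with 133 cells in 1 library and the largest immature neutrophil-like with 5072. The edgeR 4.0.16 quasi-likelihood test with TMM scaling and filterByExpr was fitted to all 6 libraries with genotype as the term, in R 4.3.3. Two-sided p-values were adjusted by Benjamini-Hochberg over all genes tested in a class, with a threshold of 0.05, for LysM-CRL against WT, LysM-CRS against WT and LysM-CRS against LysM-CRL. With 2 libraries per genotype small changes can be missed, and levels near a few UMIs per library have wide errors. In all, 27 gene lists, fixed at the same time as the markers, were tested with camera of limma 3.58.1 at a correlation of 0.01 and again with an estimated correlation, on log2 CPM with a prior count of 2. In single-gene counts a list was also adjusted on its own. Genes were named by a rule fixed beforehand: per class the 5 largest rises and 5 largest falls of each mutant against WT, and 3 and 3 between the mutants, among genes past the threshold with a mean log2 CPM of at least 5 and no overlap between the 2 groups' libraries. Predicted, clone-named, mitochondrial and ribosomal protein genes were left out, Rarg, Cpsf6, Hdac3 and Lyz2 were always included, and up to 4 members with the smallest adjusted p stand for each described list. Some genes that the rule selects are not reported here. Shares of cells were compared by exact permutation. Exact binomial intervals and an upper limit of 3 counts for a count of 0 cover counting error only.

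The difference between a class and the early progenitor-like cells of the same libraries was tested with a class-by-genotype term and a term per library. Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, each library left out in turn, the replicate number as a block, only the 2 groups compared, sums thinned to the smallest library, a stricter cell filter of at least 500 genes and under 5% mitochondrial UMIs, doublets kept, each library clustered alone, a resolution of 0.5 and an estimated correlation for lists. All libraries clustered together and clusters drawn in equal number were added after the data were seen. The rules for outliers and for other splits of samples need larger groups and were not applied. The procedure was tested on simulated data drawn from the means and dispersions of the real libraries. For LysM-CRL against WT, 52.2, 80.6, 92.5, 64.2 and 38.8% of genes changed 2-fold were recovered in early progenitor-like, granulocyte progenitor-like, immature neutrophil-like, mature neutrophil-like and monocyte-like cells, over 13279, 11998, 13187, 8602 and 8155 genes, and 7.32% to 12.9% of the genes called had not been changed, above the nominal 5%. The class-by-genotype term recovered 84, 84, 48 and 57% of 2-fold differences in the 4 classes set against early progenitor-like cells, over 14080, 14689, 13615 and 13572 genes. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9.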

Results

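Bone marrow of 12-month-old mice was profiled by droplet single-cell RNA sequencing in 6 libraries, 2 each of WT, LysM-CRL and LysM-CRS genotype. The series concerns CPSF6-RARγ, a fusion of the mRNA cleavage factor CPSF6 with the retinoic acid receptor RARγ, and the transcriptional corepressor enzyme HDAC3. In both mutants the genotype label pairs LysM-Cre, a recombinase driven from the lysozyme locus of myeloid cells, with a floxed allele called CRL or CRS; the labels do not spell out these names. Cells carrying Mac1, an integrin of myeloid cells, and cells carrying c-kit, a receptor of progenitors, were sorted and combined in equal parts before loading. The deposited UMI counts summed to 169197084 and 170593903 in the WT libraries, 148459617 and 143706649 in the LysM-CRL libraries and 73695784 and 64614059 in the LysM-CRS libraries. The median kept cell held 14002 and 13339, 10774 and 10853, and 5231 and 5622.5 UMIs in the same order. The LysM-CRS files came from another Cell Ranger version and another custom reference than the WT and LysM-CRL files, so that processing batch and genotype cannot be told apart in any comparison with LysM-CRS. The labels do not say whether replicates were separate mice, and p-values measure the spread between these libraries, which may be technical.

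The transgene transcript was examined first. FLAG-CRL, the added feature for the LysM-CRL transgene, had no UMI in 9529 and 10225 WT cells, counts that allow shares of up to 0.0315% and 0.0293% of cells with a UMI. In the LysM-CRL libraries it was found in 35.1% and 31.8% of cells (exact 95% intervals 34.1 to 36.0% and 30.9 to 32.7%, counting error only). Mature neutrophil-like cells carried it most often, at 46.6% and 48.4% of cells and 116 and 121 CPM. Monocyte-like cells stood at 45.6% and 22.5% and 109 and 54.5 CPM and immature neutrophil-like cells at 37.2% and 29.7% and 46.6 and 37.2. Early progenitor-like cells had 8.30 and 6.02 and granulocyte progenitor-like cells 5.46 and 3.34 CPM, levels at or below the 8.69 and 6.68 of lymphoid-like cells, in which a myeloid Cre should not act, and their shares of 13.4% and 11.2% and 10.7% and 7.69% are not read as expression. The lymphoid-like cells, of another makeup in each library, were 696 B, 354 NK and 0 T cell-like cells in WT 1, 660 B, 227 NK and 1 T cell-like cells in WT 2, 19 B, 25 NK and 179 T cell-like cells in LysM-CRL 1 and 173 B, 169 NK and 2 T cell-like cells in LysM-CRL 2. Of those in the LysM-CRL libraries 6.73% and 4.36% had a FLAG-CRL UMI, at median depths of 9740 and 6391 UMIs against 7246 and 7469 in mature neutrophil-like cells. With every cell thinned to 2000 UMIs, which left out 542 and 256 shallower cells, the shares were 19.8% and 21.1% in mature neutrophil-like, 17.2% and 8.22% in monocyte-like, 10.2% and 7.31% in immature neutrophil-like and 0.980% and 1.19% in lymphoid-like cells.

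In the LysM-CRS libraries the FLAG-CRS-tdtomato feature was found in 5.80% and 6.51% of cells, with 8.28% and 13% of mature neutrophil-like, 7.61% and 8.51% of immature neutrophil-like and 7.27% and 7.06% of monocyte-like cells. Their levels were 27.2 and 57.2, 13.8 and 14.8 and 16.2 and 22 CPM, and lymphoid-like cells, of which there were only 33 and 181, held 1 and 2 UMIs, a share of 3.03% and 1.10% and a level of 11.4 and 2.80 CPM, the former near that of immature neutrophil-like cells, at median depths of 2118 and 2104 UMIs against 3117 and 2461 in mature neutrophil-like cells. Early and granulocyte progenitor-like cells stood at 3.48 and 4.3 and 2.23 and 1.37 CPM. The WT and LysM-CRL files were not counted against this feature, so it has no WT background. Thinned to 2000 UMIs, the shares were 4.88% and 8.70%, 2.52% and 3.82% and 1.60% and 3.73% in mature neutrophil-like, immature neutrophil-like and monocyte-like cells, and 0% and 2.06% of the 20 and 97 lymphoid-like cells deep enough.

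**Figure D1:**
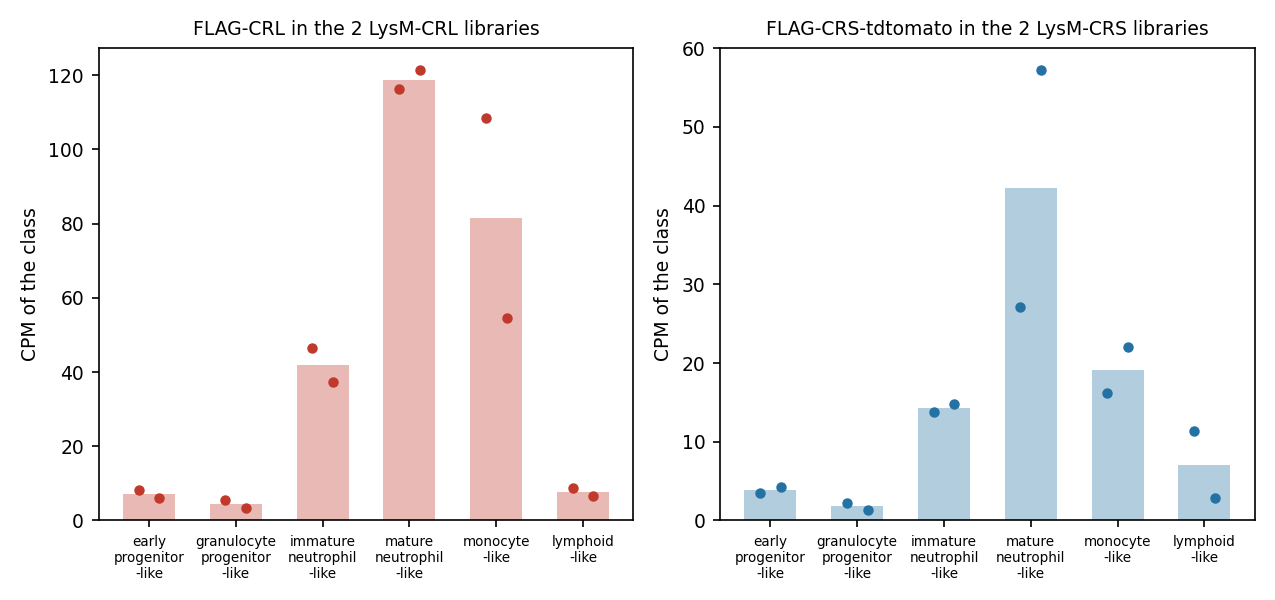
Level of the transgene feature in each cell class (vertical axis, CPM) in the LysM-CRL libraries (left, FLAG-CRL) and the LysM-CRS libraries (right, FLAG-CRS-tdtomato); points are the 2 libraries and bars their mean. Mature neutrophil-like cells stand highest in both panels, at 116 and 121 and at 27.2 and 57.2.

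Among the mouse genes named by the series, Lyz2, the lysozyme gene that carries LysM-Cre (chromosome 10, 117277331 to 117282321, GRCm38), fell in LysM-CRL immature neutrophil-like cells by 0.99 ± 0.11 and in mature neutrophil-like cells by 1.12 ± 0.13 on the log2 scale (SE, n = 2 libraries per group; adjusted p = 0.00161 and 0.00287, edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Its log2 fold changes were -0.44 in early progenitor-like, -0.40 in granulocyte progenitor-like and -0.72 in monocyte-like cells, none past the threshold. Cpsf6, which lies 62.4 kb from Lyz2 (chromosome 10, 117344673 to 117380015), rose by 0.34 ± 0.06 in immature and 0.83 ± 0.15 in mature neutrophil-like cells of LysM-CRL libraries (adjusted p = 0.0121 and 0.0273, edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Rarg (chromosome 15, 102234938 to 102257517) had log2 fold changes from -0.43 to 0.74 and Hdac3 (chromosome 18, 37935844 to 37955016) from -0.21 to 0.30 over the 5 classes, none past the threshold. In LysM-CRS libraries, where batch is confounded with genotype, Lyz2 fell in 4 classes and Cpsf6 in 3. Both fell furthest in granulocyte progenitor-like cells, to -3.86 ± 0.17 and -1.14 ± 0.10 (adjusted p = 1.94e-08 and 2.32e-06, edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Both Cpsf6 calls in LysM-CRL ended without WT 1, WT 2, LysM-CRL 1 or LysM-CRL 2. Cpsf6 then stood, in that order, at 0.33, 0.36, 0.34 and 0.34 in immature and 0.83, 0.84, 0.89 and 0.77 in mature neutrophil-like cells. A read from the end of a transcript cannot show whether a Rarg or Cpsf6 transcript came from the normal locus or the fusion, so these genes do not check the genotype labels.

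To ask how the genotypes differed in cell makeup, the share of each class among kept cells was compared. Mature neutrophil-like cells, whose clusters were led by genes such as Retnlg and Il1b, made up 6.47% ± 0.429 (SD, n = 2) of WT, 32.0% ± 3.32 of LysM-CRL and 19.1% ± 1.03 of LysM-CRS cells. Within the neutrophil series, the sum of granulocyte progenitor-like, immature and mature neutrophil-like cells, their share was 10.6% ± 0.589, 40.7% ± 2.96 and 30.6% ± 2.70. Early progenitor-like cells, marked by Cd34, Adgrl4 and Mecom, made up 10.7% ± 2.95, 3.0% ± 0.163 and 11.5% ± 3.30 of cells. In LysM-CRS 14.2% and 7.96% of them lay in Ube2c-led and 11.1% and 7.12% in Hist1h1a-led clusters. WT and LysM-CRL, clustered apart, could not join either. Granulocyte progenitor-like cells, marked by the primary granule genes Elane, Prtn3 and Mpo, made up 10.2% ± 0.231, 4.57% ± 0.220 and 10.7% ± 2.31. Monocyte-like cells stood at 1.54% ± 0.334, 6.61% ± 1.39 and 2.75% ± 1.44, and B cell-like cells at 6.88% ± 0.601, 0.983% ± 1.13 and 0.925% ± 0.967. In these 5 classes both LysM-CRL libraries lay outside the range of both WT libraries, whereas the immature neutrophil-like share, 44.5% ± 7.24, 42.0% ± 0.661 and 32.9% ± 5.56, overlapped between WT and LysM-CRL. The exact two-sided permutation p of LysM-CRL against WT was 0.333 for each of the 5, the smallest that 2 against 2 libraries allow, so no difference in shares is called.

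Megakaryocyte-like cells were 4.91%, 1.00% and 3.46% and erythroid-like cells 0.787%, 0.264% and 6.16% of WT, LysM-CRL and LysM-CRS cells, values that moved to 1.42%, 0.399% and 2.67% and 0.652%, 0.0809% and 2.02% at a cluster resolution of 0.5 and to 2.61%, 0% and 3.30% and 2.53%, 1.42% and 2.86% with each library clustered alone. Clusters left without a name by thresholds set after the clusters were seen held cells with at least as many monocyte markers (4.86%, 1.71% and 1.74% of WT, LysM-CRL and LysM-CRS cells), B cell markers (0.336%, 0.386% and 0%) or conventional dendritic cell markers (0%, 0% and 1.76%) as markers of their own class. Others had a marker score under the minimum (2.20%, 3.72% and 5.34%). The share of monocyte-like cells in WT is smaller than that of the unnamed clusters with monocyte markers, reading 0.675% with each library clustered alone and 2.48% at a resolution of 0.5. The equal mixing of sorted Mac1 and c-kit cells sets the balance of mature cells and progenitors, LysM-CRS cells held fewer UMIs, and genotype and batch were confounded for LysM-CRS. The order of LysM-CRL and LysM-CRS in the mature share of the series turned around in 3 settings: all libraries clustered together, each library clustered alone, and the stricter cell filter.

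**Figure D2:**
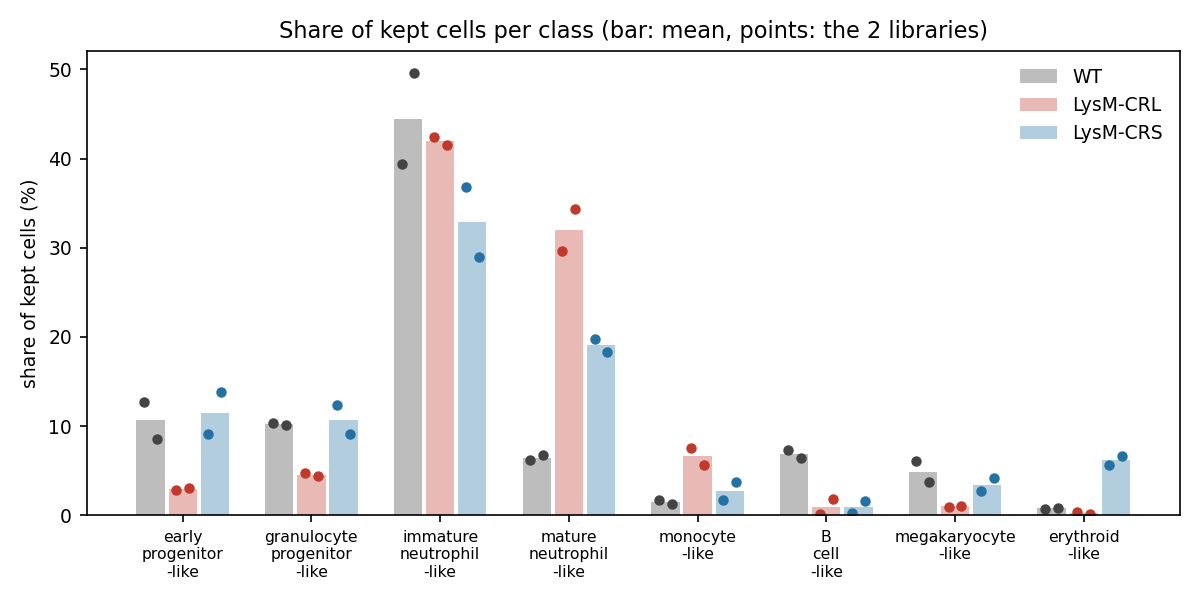
Share of kept cells (vertical axis, percent) in 8 cell classes for WT, LysM-CRL and LysM-CRS; bars are means and points the 2 libraries. Mature neutrophil-like cells have a mean of 6.47% in WT and 32.0% in LysM-CRL, and early progenitor-like cells 10.7% and 3.0%.

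To find the genes that differ with the LysM-CRL genotype, each cell class was compared between LysM-CRL and WT libraries, whose files share a Cell Ranger version and custom reference. Cyp26a1, the retinoic acid hydroxylase and a direct target of retinoic acid receptors (chromosome 19, 37697798 to 37701536), rose in neutrophils. In immature neutrophil-like cells it had 3 and 2 UMIs in the WT and 280 and 201 in the LysM-CRL libraries, a log2 fold change of 6.52 ± 0.36 (adjusted p = 4.96e-05, edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Mature neutrophil-like cells had 72 and 97 UMIs in LysM-CRL and none in WT, at least 9.07-fold higher against a floor of 3 counts over the WT group (adjusted p = 0.0155, edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Gsr, glutathione reductase (chromosome 8, 33652523 to 33698163), rose in all 5 classes, from 1.72 ± 0.15 in early progenitor-like to 3.26 ± 0.16 in mature neutrophil-like cells. It is among 102 genes called in the same direction in 3 or more classes, of which 55.4% lie within 2 Mb of another, against a median of 24.8% in random sets. Gsr also stood at 122 CPM in the B cell-like and 90.6 in the NK cell-like cells of LysM-CRL 2, against 16.9 and 21.0 and 11.6 and 29.0 in WT. Of the genes named below, Hjurp, Sec61b, Tmsb4x, Rbmxl1, Arhgap10, Alad, Ccl6, Il1r2, Trem1, Mxd1, Retnlg, S100a6, Chil1, Hmgn1, Ttc3, Mmp8, Mmp9, Itgb2l, Uqcrq, Olfm4, Cxcr4, Hes1, Stfa2l1, Vcam1, Pim1, Ppp2cb and Tnf belong to the same set. Changes are log2 fold changes ± SE from 2 libraries per group. The largest rises and falls named are those of genes with a mean log2 CPM of at least 5 whose libraries do not overlap between the groups. Of 133 calls of named genes and list members in this comparison, 64, 65, 45 and 30 ended without WT 1, WT 2, LysM-CRL 1 or LysM-CRL 2, and none changed sign. Among them were Cyp26a1 in mature neutrophil-like cells (adjusted p = 0.0737 without WT 1 and 0.114 without WT 2) and Gsr in early progenitor-like cells (adjusted p = 0.0544 and 0.0505, edgeR quasi-likelihood test, Benjamini-Hochberg adjustment).

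In early progenitor-like cells 41 genes rose and 15 fell of 13735 tested. Beside Gsr, the largest rises were of Hjurp, the chaperone that loads the centromeric histone (1.33 ± 0.12), Sec61b, a subunit of the protein channel of the endoplasmic reticulum (1.27 ± 0.14), the actin-binding Tmsb4x (1.26 ± 0.13) and Rbmxl1 (1.22 ± 0.14). Rbmxl1 is a copy of the RNA-binding Rbmx gene, whose reads may be shared with it. Arhgap10 (-1.02 ± 0.15) and Alad, an enzyme of heme synthesis (-1.0 ± 0.15), were among the falls. Adjusted p values of these 7 genes ran from 0.00659 to 0.0441 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Of 22 mature neutrophil genes, 4 rose and 18 did when adjusted over the list alone (adjusted p = 7.20e-15 in camera, adjusted p = 0.292 with an estimated correlation): the chemokine Ccl6 3.22, the decoy receptor Il1r2 1.66, Trem1 1.53 and Mxd1 0.94. When WT 1, WT 2, LysM-CRL 1 or LysM-CRL 2 was left out, 4, 4, 1 and 0 of the 4 calls ended. Lymphoid-like cells of the same libraries also held more of these transcripts, with 0.0105 and 0.0135 Ccl6 UMIs per cell in WT and 0.148 and 0.166 in LysM-CRL. None of 22 stem cell and Hox genes passed, with 5 at an unadjusted p under 0.05 in edgeR, 1 called by DESeq2 and 1 fallen when adjusted over the list alone. Camera placed the list lower (adjusted p = 9.62e-04 in camera, adjusted p = 0.477 with an estimated correlation), a call that ended without LysM-CRL 1 (adjusted p = 0.347). Hmga2 was at -1.78 and Hoxa9 at -0.43. The cluster led by Il1rapl2 and Mecom held 28% and 25.4% of this class in WT but 7.53% and 39.3% in LysM-CRL 1 and 2. With each library clustered alone the count of changed genes was 0. There 455 of 14550 genes had an unadjusted p under 0.05 in edgeR, fewer than would be expected without any change, and DESeq2 was not run.

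Granulocyte progenitor-like cells had 255 genes higher and 91 lower of 12479 tested. The neutrophil resistin-like gene Retnlg (3.52 ± 0.31), the calcium-binding S100a6 (3.22 ± 0.33), Ifitm6 (1.85 ± 0.35), Gsr (1.78 ± 0.10) and Hjurp (1.52 ± 0.14) rose most. The chitinase-like Chil1 (-1.89 ± 0.25), Pttg1, the securin of sister chromatid separation (-1.59 ± 0.14), the nucleosome-binding Hmgn1 (-1.18 ± 0.14) and Ttc3 (-0.98 ± 0.11) were among the largest falls, at adjusted p from 2.62e-06 to 0.0170 over the 9 genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Of 22 mature neutrophil genes 13 rose (17 adjusted over the list alone; adjusted p = 7.33e-13 in camera, adjusted p = 0.414 with an estimated correlation). Il1r2, Ccl6 and Il1b stood at 3.79, 2.36 and 2.84. Among 20 secondary and tertiary granule genes 6 rose and 1 fell (14 and 2 adjusted over the list alone; adjusted p = 3.66e-07 in camera, adjusted p = 0.414 with an estimated correlation). The collagenase Mmp8 was at 4.04, the gelatinase Mmp9 at 3.59, Padi4, which citrullinates histones, at 1.26 and the cathelicidin Camp at 1.31. Interferon response genes had 4 of 19 members higher (9 adjusted over the list alone; adjusted p = 1.20e-05 in camera, adjusted p = 0.414 with an estimated correlation). Rsad2, Bst2 and Zbp1 stood at 1.95, 0.85 and 1.70. Inflammatory cytokine and NF-kB genes had 5 of 18 (10 adjusted over the list alone; adjusted p = 5.69e-07 in camera, adjusted p = 0.414 with an estimated correlation). Osm, Ptgs2 and Il1rn stood at 1.5, 1.76 and 2.44. Immediate early genes rose in 4 of 16 (11 adjusted over the list alone; adjusted p = 2.42e-07 in camera, adjusted p = 0.414 with an estimated correlation). Btg2, Junb and Klf6 stood at 1.11, 0.81 and 0.71. The cluster led by Elane, Prtn3 and Ctsg held 50.1% and 48.7% of this class in WT and 38.9% and 38.5% in LysM-CRL, and that led by Elane, Ms4a3 and Fcnb held 32.3% and 36.3% and 43.1% and 51.5%. Beside these rises, lymphoid-like cells held 0.207 and 0.939 Retnlg UMIs per cell in WT and 7.28 and 7.89 in LysM-CRL. The gain in UMIs per cell over WT in LysM-CRL 1 and 2 was 1.90 and 1.47 times that of lymphoid-like cells for Retnlg, 1.13 and 0.898 for Mmp8, 1.58 and 0.734 for Mmp9, 1.25 and 4.69 for Il1b, 2.62 and 2.58 for Ccl6, 5.04 and 2.21 for Padi4, 9.41 and 3.55 for Il1r2 and 33.5 and 16.3 for Camp. With WT 1, WT 2, LysM-CRL 1 or LysM-CRL 2 left out, 5, 3, 3 and 2 of the 13 mature neutrophil calls ended, 5, 3, 3 and 1 of the 7 granule, 4, 2, 4 and 1 of the 4 interferon, 2, 3, 2 and 1 of the 5 cytokine and 1, 3, 3 and 0 of the 4 immediate early calls. Without WT 1, WT 2, LysM-CRL 1 or LysM-CRL 2 the count was 115, 149, 181 or 219. With each library clustered alone the count was 4.

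Immature neutrophil-like cells, the most numerous class, had 1347 genes higher and 935 lower of 13581 tested, 253 and 173 of them by at least 2-fold. Itgb2l, an integrin subunit of neutrophils (2.43 ± 0.07), Gsr (2.37 ± 0.08), the kinase Map4k4 (1.79 ± 0.17), Mmp8 (1.58 ± 0.15) and S100a6 (1.52 ± 0.23) rose most. Herpud1, of endoplasmic reticulum quality control (-1.15 ± 0.07), Lyz2 (-0.99 ± 0.11), the respiratory complex III subunit Uqcrq (-0.82 ± 0.08), the granule protein Olfm4 (-0.71 ± 0.20) and Tecr, of very long chain fatty acid synthesis (-0.70 ± 0.08), fell most, at adjusted p from 2.15e-06 to 0.0459 over the 10 genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Mitosis genes fell together, 17 of 22 (21 adjusted over the list alone; adjusted p = 2.87e-09 in camera, adjusted p = 0.598 with an estimated correlation). The cyclin Ccnb2 was at -0.58 and Ccnb1 at -0.51 and the anaphase regulators Ube2c at -0.58 and Cdc20 at -0.57. Mature neutrophil genes rose in 14 of 22 (16 adjusted over the list alone; adjusted p = 1.19e-06 in camera, adjusted p = 0.598 with an estimated correlation). The marrow-retention receptor Cxcr4 was at 1.41 and Ccl6 at 2.56. Lymphoid-like cells held 0.0105 and 0.0135 Ccl6 UMIs per cell in WT and 0.148 and 0.166 in LysM-CRL. The cluster led by Ly6g, Ltf and Mmp9 held 35.9% and 31.7% of this class in LysM-CRL and 9.76% and 13% in WT, and that led by Spc25 and Top2a held 25.6% and 27.1% and 42.0% and 37.7%. With clusters drawn in equal number the mitosis call ended (adjusted p = 0.210 in camera), a setting added after the data were seen, as did 16 of 17 single mitosis and 7 of 14 mature neutrophil calls. Calls that ended without WT 1, WT 2, LysM-CRL 1 or LysM-CRL 2 were 14, 13, 13 and 13 of the 17 for mitosis and 12, 11, 10 and 6 of the 14 for mature neutrophil genes.

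Further lists moved in the LysM-CRL immature neutrophil-like cells. Inflammatory cytokine and NF-kB genes rose in 10 of 18 members (11 adjusted over the list alone; adjusted p = 1.84e-05 in camera, adjusted p = 0.598 with an estimated correlation). The interleukin 1 antagonist Il1rn was at 1.62, the prostaglandin synthase Ptgs2 at 1.83 and the chemokine Ccl2 at 2.92. Immediate early genes rose in 8 of 17 (11 adjusted over the list alone; adjusted p = 1.18e-05 in camera, adjusted p = 0.598 with an estimated correlation). Nr4a1, Ier5 and Junb stood at 1.61, 0.73 and 1.31. Targets of p53 and cell death genes rose in 9 of 17 (11 adjusted over the list alone; adjusted p = 1.84e-05 in camera, adjusted p = 0.598 with an estimated correlation). Perp was at 1.80, Trp53inp1 at 0.85, the BH3 protein gene Pmaip1 at 1.45 and Sesn2 at 0.89. Oxidative phosphorylation genes fell in 7 of 21 (9 adjusted over the list alone; adjusted p = 1.61e-04 in camera, adjusted p = 0.598 with an estimated correlation). Sdha, Ndufs3 and Uqcrfs1 stood at -0.41, -0.30 and -0.27. Ribosome biogenesis genes fell in 4 of 20 (5 adjusted over the list alone; adjusted p = 0.00132 in camera, adjusted p = 0.598 with an estimated correlation). Nop16, Nop58 and Pa2g4 stood at -3.43, -0.48 and -0.32. Of 7 retinoic acid receptor targets tested, Cyp26a1 and the surface enzyme Cd38 (1.72 ± 0.44) rose (2 rose and 1 fell adjusted over the list alone), while the list as a whole did not pass (adjusted p = 0.370 in camera, adjusted p = 0.598 with an estimated correlation). Leaving out WT 1, WT 2, LysM-CRL 1 or LysM-CRL 2 in turn, 7, 7, 7 and 7 of the 7 oxidative phosphorylation calls ended, 8, 9, 8 and 7 of the 10 cytokine, 2, 4, 2 and 2 of the 8 immediate early, 6, 6, 5 and 5 of the 9 p53 and 3, 3, 3 and 3 of the 4 ribosome biogenesis calls. With matched clusters 3 of 7, 2 of 10, 2 of 8, 3 of 9 and 3 of 4 of these ended, in that order. Without WT 1, WT 2, LysM-CRL 1, LysM-CRL 2, LysM-CRS 1 or LysM-CRS 2 the count was 275, 369, 399, 606, 3942 or 3914, and with only the WT and LysM-CRL libraries fitted it was 4009.

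Mature neutrophil-like cells had 136 genes higher and 112 lower of 9096 tested. Hjurp (3.32 ± 0.17), Gsr (3.26 ± 0.16), the retinol dehydrogenase Rdh12 (2.75 ± 0.15), Itgb2l (2.05 ± 0.14) and the interferon-induced Ifitm1 (1.90 ± 0.36) rose most. Herpud1 (-1.89 ± 0.17), Sap30, a subunit of a histone deacetylase complex (-1.75 ± 0.17), the homeodomain protein gene Hopx (-1.60 ± 0.14), Tecr (-1.46 ± 0.13) and Krt83 (-1.33 ± 0.21) fell most, at adjusted p from 2.78e-05 to 0.0288 over the 10 genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Of 5 retinoic acid receptor targets Cyp26a1 rose (2 adjusted over the list alone), Dhrs3 was at 0.67 and Cd38 at 1.29. The list passed (adjusted p = 0.0418 in camera, adjusted p = 0.613 with an estimated correlation) but not without WT 2 (adjusted p = 0.167) or with each library clustered alone (adjusted p = 0.157). Of 20 interferon response genes Gbp2 rose (2.04; 2 adjusted over the list alone), and the call of the list (adjusted p = 0.00213 in camera, adjusted p = 0.865 with an estimated correlation) ended without WT 1 or LysM-CRL 1 (adjusted p = 0.577 and 0.473). Camera placed oxidative phosphorylation genes (adjusted p = 2.63e-04 in camera, adjusted p = 0.613 with an estimated correlation) and ribosome biogenesis genes (adjusted p = 4.08e-04 in camera, adjusted p = 0.865 with an estimated correlation) lower, with 0 of 21 and 0 of 16 members called by edgeR over all genes or adjusted over the list alone, 10 and 6 at an unadjusted p under 0.05, and 0 called by DESeq2 in either. Ndufv1 stood at -0.83 and Nop58 at -1.01. Without WT 1, WT 2 or LysM-CRL 1 the count was 81, 65 or 103.

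Monocyte-like cells had 117 genes higher and 196 lower of 8612 tested. Hes1, a Notch target (-2.93 ± 0.18), the scavenger receptor Cd36 (-2.87 ± 0.25), the lipid-sensing receptor Pparg (-2.85 ± 0.19), the class II gene H2-Eb1 (-2.49 ± 0.41) and the survival gene Bcl2 (-2.37 ± 0.20) fell most. Retnlg (3.02 ± 0.30), Mmp8 (2.91 ± 0.32), Gsr (2.86 ± 0.25), Vcan, a proteoglycan of classical monocytes (2.54 ± 0.25), and Ier3 (1.99 ± 0.23) rose most, at adjusted p from 2.60e-04 to 0.0146 over the 10 genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Class II antigen presentation genes fell in 4 of 8 (7 adjusted over the list alone; adjusted p = 7.52e-05 in camera, adjusted p = 0.664 with an estimated correlation). H2-Ab1, H2-Aa and Cd74 stood at -2.32, -2.24 and -1.97. Mature neutrophil genes rose in 7 of 22 (8 rose and 1 fell adjusted over the list alone; adjusted p = 0.00250 in camera, adjusted p = 0.664 with an estimated correlation). Slpi was at 1.53. Stfa2l1, one of several near-identical stefin genes, had 0 and 1 UMIs in WT and 235 and 184 in LysM-CRL, a ratio of 50.5 (counting interval 9.02 to 2000). Lymphoid-like cells held 0.207 and 0.939 Retnlg UMIs per cell in WT and 7.28 and 7.89 in LysM-CRL. S100 genes rose in 3 of 7 (4 adjusted over the list alone; adjusted p = 0.0146 in camera, adjusted p = 0.664 with an estimated correlation). S100a6, S100a4 and S100a10 stood at 1.28, 1.09 and 1.51. The cluster led by Fn1, Ccr2 and Vcan held 90.5% and 90.5% of this class in LysM-CRL and 63.3% and 50.4% in WT, and that led by Adgre4, Cd36 and Pparg the rest. With clusters drawn in equal number Pparg was at -0.96 and Cd36 at -1.01, the latter no longer past the threshold. With WT 1, WT 2, LysM-CRL 1 or LysM-CRL 2 left out, 3, 4, 4 and 0 of the 4 class II calls ended, 4, 4, 4 and 3 of the 7 mature neutrophil and 1, 3, 2 and 2 of the 3 S100 calls. Without WT 1, WT 2, LysM-CRL 1, LysM-CRL 2, LysM-CRS 1 or LysM-CRS 2 the count was 126, 56, 40, 66, 1009 or 1010, and with only the WT and LysM-CRL libraries fitted it was 1009. Without WT 1 the calls of the mature neutrophil and S100 lists ended.

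**Figure D3:**
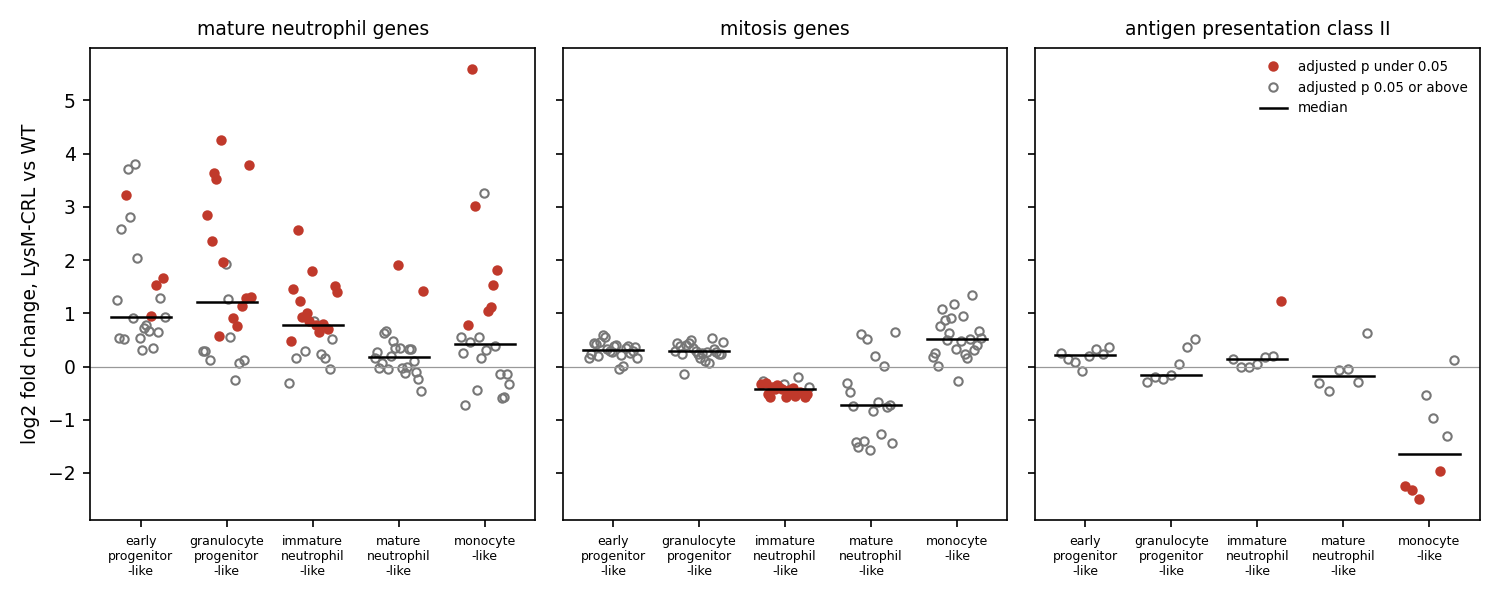
Log2 fold change of LysM-CRL against WT (vertical axis) for each tested member of 3 gene lists in 5 cell classes; filled points passed an adjusted p of 0.05 and bars are medians. Filled points of the mature neutrophil list lie above 0, 14 of 22 in immature neutrophil-like cells, and those of the mitosis list below 0 there, 17 of 22.

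To find genes that differ in LysM-CRS, the same classes were compared with WT libraries, although batch and genotype cannot be told apart here. The LysM-CRS libraries, clustered on their own, filled clusters that hold no WT cell. Genes higher and lower numbered 3596 and 4349 of 13735 tested in early progenitor-like, 3948 and 4443 of 12479 in granulocyte progenitor-like, 3989 and 4716 of 13581 in immature neutrophil-like, 2313 and 2599 of 9096 in mature neutrophil-like and 1742 and 2094 of 8612 in monocyte-like cells. Lrmda, a gene of large introns, fell in early progenitor-like (-5.41 ± 0.60), granulocyte progenitor-like (-4.77 ± 0.52), immature neutrophil-like (-5.72 ± 0.46) and monocyte-like cells (-6.25 ± 0.47). Taf10, a short gene of the general transcription machinery, rose by 4.20 ± 0.25 and 4.21 ± 0.14 in early and granulocyte progenitor-like cells. Genes with over 100 kb of intron had a median log2 fold change of -1.58 in early progenitor-like and -1.55 in monocyte-like cells, against 0.53 and 0.69 for genes with under 2 kb or none. In LysM-CRL this gap was -0.16 and -0.41 there, -0.0077 in granulocyte progenitor-like and 0.14 and 0.21 in immature and mature neutrophil-like cells.

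**Figure D4:**
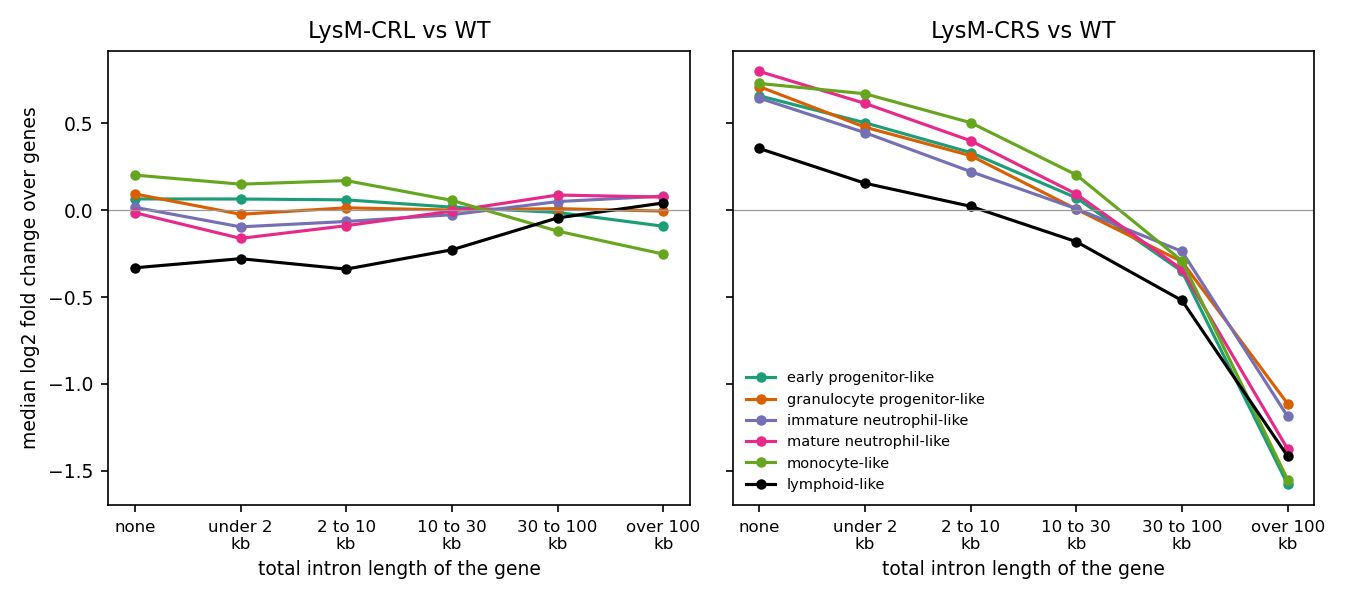
Median log2 fold change (vertical axis) of genes grouped by total intron length, genes without introns apart, (horizontal axis) in each cell class, for LysM-CRL (left) and LysM-CRS (right) against WT; each line is a class, lymphoid-like cells included. The LysM-CRS medians in the 5 tested classes lie above 0 for short and below 0 for long introns.

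In LysM-CRS early progenitor-like cells, where batch and genotype cannot be told apart, Lars2, the mitochondrial leucyl-tRNA synthetase (4.23 ± 0.20), the splicing factor Srsf9 (3.45 ± 0.13), the mRNA export factor Alyref (3.26 ± 0.17) and Ppp1r14b (3.20 ± 0.18) were among the largest rises. The potassium channel gene Kcnq5 (-5.90 ± 0.19), Mir142hg, host of a hematopoietic microRNA (-5.79 ± 0.15), Zswim6 (-5.14 ± 0.26) and the exchanger gene Slc9a9 (-4.93 ± 0.14) were among the largest falls, at adjusted p from 3.75e-06 to 2.34e-04 over these and Taf10 and Lrmda (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Ribosome biogenesis genes rose in 15 of 20 (15 adjusted over the list alone; adjusted p = 0.00447 in camera, adjusted p = 0.910 with an estimated correlation). Odc1, Nop16 and Ldha stood at 1.51, 1.45 and 0.98. Monocyte and macrophage genes fell in 12 of 19 (13 adjusted over the list alone; adjusted p = 0.0200 in camera, adjusted p = 0.910 with an estimated correlation). The monocyte transcription factor Irf8 was at -2.79, F13a1 at -2.43 and Cx3cr1 at -2.17, a call that ended with each library clustered alone (adjusted p = 0.348 in camera, with 846 genes changed).

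In granulocyte progenitor-like cells of LysM-CRS libraries, with batch and genotype again confounded, Ifitm1 (4.82 ± 0.52), S100a6 (4.32 ± 0.34), Alyref (3.98 ± 0.13) and Retnlg (3.90 ± 0.32) rose. Fcnb, a ficolin of neutrophil granules (-5.41 ± 0.18), Mir142hg (-5.28 ± 0.13), Abca13 (-4.86 ± 0.20) and the adhesion molecule Vcam1 (-4.73 ± 0.23) fell, at adjusted p from 2.82e-09 to 9.90e-06 over these and Taf10 and Lrmda (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). All 20 ribosome biogenesis genes tested rose (20 adjusted over the list alone; adjusted p = 8.53e-06 in camera, adjusted p = 0.976 with an estimated correlation). Pa2g4, Gnl3 and Srm stood at 1.52, 1.65 and 1.90. Secondary and tertiary granule genes fell in 16 of 20 and rose in 2 (16 and 2 adjusted over the list alone; adjusted p = 0.00356 in camera, adjusted p = 0.976 with an estimated correlation). Olfm4 was at -4.38 and the oxidase subunit Cybb at -3.63. With each library clustered alone the list's call ended (adjusted p = 0.0729 in camera) and 4418 genes changed.

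Immature neutrophil-like cells of the LysM-CRS libraries, where batch and genotype cannot be told apart, had higher Cebpb, the transcription factor of stress granulopoiesis (4.67 ± 0.20), the histone gene Hist1h4h (3.91 ± 0.45), the kinase Pim1 (3.35 ± 0.34), S100a6 (3.29 ± 0.25) and Retnlg (3.24 ± 0.17). Cmss1 (-6.13 ± 0.28), Arl15 (-4.80 ± 0.13), the signaling adaptor Gab2 (-4.3 ± 0.18) and Mir142hg (-4.12 ± 0.10) fell, at adjusted p from 2.69e-07 to 1.28e-04 over these and Lrmda (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Mature neutrophil genes rose in 19 of 22 (19 adjusted over the list alone; adjusted p = 7.11e-05 in camera, adjusted p = 0.910 with an estimated correlation). Cxcr4, Mxd1 and Clec4d stood at 1.71, 1.99 and 2.77. All 7 S100 genes tested rose there (7 adjusted over the list alone; adjusted p = 0.00162 in camera, adjusted p = 0.910 with an estimated correlation). S100a4 was at 3.42 and S100a10 at 3.05. In mature neutrophil-like cells Hjurp (4.16 ± 0.17), Ppp2cb, a phosphatase subunit 33.1 kb from Gsr (3.89 ± 0.16), Cebpb (3.56 ± 0.22), Gsr (3.15 ± 0.16) and Rdh12 (3.14 ± 0.15) rose. Cmss1 (-7.62 ± 0.39), the synaptic scaffold gene Gphn (-6.46 ± 0.35), Fmnl2 (-5.80 ± 0.30), Arfgef2 (-4.79 ± 0.26) and Gab2 (-4.74 ± 0.15) fell there, at adjusted p from 1.32e-06 to 5.04e-06 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), in the same confounded design. S100 genes rose in 5 of 7 (5 adjusted over the list alone; adjusted p = 0.0164 in camera, adjusted p = 0.819 with an estimated correlation). Heat shock genes rose in 8 of 10 (10 adjusted over the list alone; adjusted p = 0.00623 in camera, adjusted p = 0.819 with an estimated correlation). Hspd1 and Hspe1 stood at 2.05 and 2.52. Hspa1b, whose reads may be shared with the near-identical Hspa1a, had no UMI in WT and 35 and 21 in LysM-CRS, at least 14.7-fold higher against 3 counts over the WT group.

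LysM-CRS monocyte-like cells, compared with WT in the same confounded design, had lower Rasgef1b (-6.98 ± 0.36), Cd83, an activation marker of antigen-presenting cells (-6.21 ± 0.30), the phosphatase gene Phlpp1 (-6.03 ± 0.37) and Cmss1 (-5.83 ± 0.40). Among the genes that rose were Hist1h1b 4.56, Hist1h2ae 3.99, Hist1h3e 3.98, Hist1h2ap 3.81 and Hist1h1e 3.73, similar histone gene copies whose reads may be shared, and adjusted p over these and Lrmda ran from 9.06e-06 to 9.34e-04 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Inflammatory cytokine and NF-kB genes fell in 15 of 19 and rose in 2 (15 and 2 adjusted over the list alone; adjusted p = 3.68e-05 in camera, adjusted p = 0.339 with an estimated correlation). The NF-kB inhibitor Tnfaip3 was at -4.64, Tnf at -4.31 and Ccl3 at -3.01. Immediate early genes fell in 14 of 17 and rose in 1 (14 and 1 adjusted over the list alone; adjusted p = 2.99e-04 in camera, adjusted p = 0.643 with an estimated correlation). Egr1 was at -5.07 and Dusp2 at -3.34. The WT class drew 63.3% and 50.4% of its cells from the Fn1 and Ccr2 cluster, while the LysM-CRS libraries, clustered on their own, drew 57.6% and 83.4% from a first and 24.2% and 3.07% from a second cluster led by Fn1 and S100a4.

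To ask whether the mutants differ, LysM-CRS was compared with LysM-CRL directly, with batch and genotype confounded throughout. Counts of genes higher and lower were 3423 and 4275 in early progenitor-like, 3889 and 4478 in granulocyte progenitor-like, 3776 and 4561 in immature neutrophil-like, 2567 and 2765 in mature neutrophil-like and 1670 and 1955 in monocyte-like cells. Taf10 was the largest rise in early progenitor-like (4.27 ± 0.26), granulocyte progenitor-like (4.46 ± 0.15) and monocyte-like cells (4.04 ± 0.21), and Cebpb in immature (3.92 ± 0.19) and mature neutrophil-like cells (3.65 ± 0.22). The largest falls were of Kcnq5 in early progenitor-like (-5.82 ± 0.19), Fcnb in granulocyte progenitor-like (-5.61 ± 0.18), Cmss1 in immature (-7.02 ± 0.28) and mature neutrophil-like (-8.40 ± 0.39) and Rasgef1b in monocyte-like cells (-6.12 ± 0.36). Their adjusted p ran from 6.92e-09 to 2.29e-05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Further early progenitor-like changes were Lars2 3.88, Srsf9 3.49, Mir142hg -5.52 and Lrmda -5.41, and granulocyte progenitor-like ones Ppp1r14b 3.80, Alyref 3.78, Mir142hg -5.30 and Abca13 -5.13. Immature neutrophil-like cells had Hist1h4h 3.67, Hist1h2bj 3.07, Lrmda -5.78 and Arl15 -5.02, mature neutrophil-like cells Hist1h1e 3.45, Npm1 3.36, Gphn -7.53 and Fmnl2 -5.62, and monocyte-like cells Hist1h1e 3.37, Alyref 3.10, Lrmda -6.08 and Zc3h12c -5.76.

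Gene lists also differed between the mutants, in the same confounded design. Secondary and tertiary granule genes were lower in LysM-CRS granulocyte progenitor-like cells in 18 of 20 (18 adjusted over the list alone; adjusted p = 1.5e-05 in camera, adjusted p = 0.966 with an estimated correlation). Chil3 and Cybb stood at -4.27 and -4.03. All 7 S100 genes were higher in immature neutrophil-like cells (7 adjusted over the list alone; adjusted p = 0.0112 in camera, adjusted p = 0.988 with an estimated correlation). S100a10 and S100a4 stood at 3.38 and 1.23. DNA replication genes were higher in LysM-CRS mature neutrophil-like cells in 14 of 19 (14 adjusted over the list alone; adjusted p = 0.00127 in camera, adjusted p = 0.831 with an estimated correlation). Dut, Hells and Mcm6 stood at 4.01, 3.51 and 2.13. Retinoic acid receptor targets were lower there in 4 of 5 (4 adjusted over the list alone; adjusted p = 0.0438 in camera, adjusted p = 0.756 with an estimated correlation). Cyp26a1 was at -2.88, with 1 and 3 UMIs in LysM-CRS, Dhrs3 at -1.52, Tgm2 at -1.93 and Cebpe at -1.23. In monocyte-like cells 17 of 19 inflammatory cytokine and NF-kB genes were lower (17 adjusted over the list alone; adjusted p = 1.36e-08 in camera, adjusted p = 0.166 with an estimated correlation). Tnfaip3, Tnf and Nfkbiz stood at -4.75, -4.40 and -3.80. The retinoic acid list's call ended without WT 1 or LysM-CRS 2 (adjusted p = 0.0517 and 0.0561 in camera), and with no filter on low counts or each library clustered alone (adjusted p = 0.151 and 0.189), as did the S100 list's with each library clustered alone (adjusted p = 0.0546). Without LysM-CRL 1 or 2 the count of genes in monocyte-like cells was 2022 or 1728, and with each library clustered alone those in early and granulocyte progenitor-like cells were 692 and 4621.

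To ask how far the mutants change alike, their log2 fold changes against WT were correlated across genes, which are not independent replicates. Pearson's r was 0.202 in early progenitor-like, 0.130 in granulocyte progenitor-like, 0.222 in immature neutrophil-like, 0.253 in mature neutrophil-like and 0.481 in monocyte-like cells. Since both contrasts used the same WT libraries, 100 simulated data sets without effects gave mean r of 0.412, 0.375, 0.281, 0.598 and 0.606. The covariance was 0.206, 0.121, 0.279, 0.267 and 0.522, above the simulated 0.0491, 0.0338, 0.0378, 0.0836 and 0.0935 by 0.157, 0.0871, 0.241, 0.184 and 0.428. With 1 library left out it ran from 0.177 to 0.390, 0.0426 to 0.239, 0.295 to 0.376, 0.286 to 0.764 and 0.550 to 0.963, and with the stricter cell filter it was 0.136 in early and 0.0533 in granulocyte progenitor-like cells, where the highest simulated values were 0.0543 and 0.0397. Pearson's r in early progenitor-like cells was 0.128 without LysM-CRL 1. In monocyte-like cells, 179 of 196 LysM-CRL falls, Cd36 and Pparg among those tested, were shared with LysM-CRS, against 47.7 for independent lists. Of 117 rises 74 were, against 23.7. Immature neutrophil-like cells shared 693 of 1347 rises and 500 of 935 falls, against 396 and 325, and mature neutrophil-like cells 86 of 136 and 80 of 112, against 34.6 and 32.0, with Hjurp, Gsr and Rdh12 among the shared rises. Granulocyte progenitor-like cells shared 106 of 255 rises and 65 of 91 falls, against 80.7 and 32.4, and early progenitor-like cells 21 of 41 and 15 of 15, against 10.7 and 4.75. Opposite calls in LysM-CRS met 8 and 0 of the LysM-CRL rises and falls in early progenitor-like, 77 and 14 in granulocyte progenitor-like, 379 and 184 in immature neutrophil-like, 25 and 15 in mature neutrophil-like and 14 and 0 in monocyte-like cells. Part of each excess may come from the shared WT libraries. Makeup may add to it in monocyte-like cells. Clusters led by genes such as Ace held 36.7% and 49.6% in WT, 9.51% and 9.51% in LysM-CRL and 18.2% and 13.5% in LysM-CRS. In a test chosen after the data were seen, with LysM-CRL taken against WT 1 and LysM-CRS against WT 2, the covariance was 0.131, 0.0153, 0.238, 0.228 and 0.404, and the other way round 0.155, 0.15, 0.255, 0.304 and 0.485, in the order of classes above.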

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

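Chosen only after the result was seen were the tests of intron length, of depth, of WT libraries in the LysM-CRS batch, of gene position, of lymphoid-like cells for the genes shared by classes, and of free RNA, with B cell-like and NK cell-like cells also taken apart.

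The change of several genes named in the report differed between a cell class and the early progenitor-like cells of the same libraries. Given is the log2 change in the class minus that in early progenitor-like cells, for genes that passed the class-by-genotype term (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). In LysM-CRL against WT the term passed at 39, 150, 424 and 410 genes of granulocyte progenitor-like, immature neutrophil-like, mature neutrophil-like and monocyte-like cells. In granulocyte progenitor-like cells the difference was 1.2 for S100a6, -2.09 for Chil1, -0.98 for Pttg1 and -0.95 for Hmgn1. Immature neutrophil-like cells differed in Map4k4 by 1.89, Herpud1 by -1.21 and Tecr by -0.80. Mature neutrophil-like cells differed in Hjurp (2.00), Gsr (1.56), Rdh12 (1.94), Ifitm1 (1.37), Herpud1 (-1.95), Sap30 (-1.67), Tecr (-1.56) and Krt83 (-1.66). Monocyte-like cells stood apart in Gsr (1.15), Ier3 (1.61), Hes1 (-2.36), H2-Eb1 (-2.70) and Bcl2 (-2.78). Adjusted p over these genes ran from 1.96e-08 to 0.0128 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment).

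In LysM-CRS against WT, with batch and genotype confounded, the median difference over all genes was 0.183 in mature neutrophil-like cells (0.213 against LysM-CRL), so values there are read against that shift. Granulocyte progenitor-like cells differed from early progenitor-like ones in Ifitm1 (2.66), S100a6 (2.84), Alyref (0.74), Retnlg (3.22), Mir142hg (0.53) and Lrmda (0.76). The same difference in immature neutrophil-like cells was 1.05 for Cebpb, 0.81 for Hist1h4h, 1.92 for Pim1, 1.88 for S100a6, 2.58 for Retnlg, -4.02 for Cmss1, -0.87 for Arl15 and 1.68 for Mir142hg. For mature neutrophil-like cells it was 2.74 for Hjurp, 2.19 for Ppp2cb, 3.02 for Gsr, 3.21 for Rdh12, -5.55 for Cmss1, -2.61 for Gphn, -3.38 for Fmnl2 and -3.66 for Arfgef2, and for monocyte-like cells 2.53 for Hist1h1b, 1.90 for Hist1h2ae, 1.93 for Hist1h3e, 1.72 for Hist1h2ap, 1.13 for Hist1h1e, -5.16 for Rasgef1b and -3.70 for Cmss1. Between the mutants, granulocyte progenitor-like cells differed in Ppp1r14b (0.71) and Alyref (0.70), immature neutrophil-like in Hist1h4h (0.89), Hist1h2bj (1.66), Cmss1 (-4.76) and Arl15 (-1.11), mature neutrophil-like in Hist1h1e (0.86), Npm1 (2.44), Cmss1 (-6.16), Gphn (-3.72) and Fmnl2 (-2.92) and monocyte-like cells in Hist1h1e (0.74), Rasgef1b (-3.93) and Zc3h12c (-4.21). Adjusted p ran from 6.30e-13 to 0.0273 against WT and from 5.38e-14 to 0.0345 between the mutants (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment).

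The added feature tdtomato, used in no comparison, had UMIs in 2.26% and 2.24% of LysM-CRL cells, whereas it had none in 9529 and 10225 WT cells (shares of up to 0.0315% and 0.0293%). Mature neutrophil-like cells held 3.88 and 4.32 CPM of it and lymphoid-like cells 0.915 and 0.636, from 2 UMIs in each library.

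LysM-CRS libraries differed from WT at many genes in every tested class, lower for genes of long introns. The tables argue against lower depth as the whole cause, since at least 81.8% of the genes called in each class were still called with all libraries thinned to the smallest. Lymphoid-like and immature neutrophil-like changes correlated at 0.674 across genes, which are not independent (0.490 in LysM-CRL, 0.200 between WT 1 and 2). The values were 0.590 and 0.613 for genes highest in B cell-like cells, with no shared library. The batch is in both changes, so they cannot tell where the transgene acts. A larger part of intronic reads in the WT and LysM-CRL counts is a candidate explanation, because genes with over 100 kb of intron had a median log2 change below that of genes with under 2 kb by a gap of -2.11 in early progenitor-like, -1.64 in granulocyte progenitor-like, -1.68 in immature neutrophil-like, -2.01 in mature neutrophil-like and -2.25 in monocyte-like cells. The LysM-CRS genotype acting in every class stays open, and it cannot be told apart from the batch because no WT library shared that batch.

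In LysM-CRL cells 102 genes changed in the same direction in 3 or more of the 5 classes, 66 up and 36 down, 13 of them in all 5. The members that fell argue against a transgene acting only in cells that express LysM, since their median log2 change was -0.53 in the 173 B cell-like and -0.41 in the 169 NK cell-like cells of LysM-CRL 2, the only one with 100 or more of each, against -0.067 and -0.00080 over all genes. To limit free RNA, members no lower in these cells than in the 5 classes of 1 WT library were taken against the other, at -1.24 and -1.30 (7 and 7 genes; all such genes -0.12 and -0.13) in B cell-like and -0.17 and -0.54 (6 and 5 genes; all such genes 0.074 and -0.00058) in NK cell-like cells, so that free RNA stays open in the latter. Alleles of another strain background carried by the LysM-CRL mice are a candidate explanation: 55.4% of the genes lie within 2 Mb of another, against a median of 24.8% and a highest of 42.6% in 1000 random sets, and chromosomes 8, 16 and 1 hold 19, 13 and 12. The labels name no strain, so this stays open as a hypothesis, beside an effect of the genotype in all cells, which was not tested.

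Of 22 mature neutrophil genes, 4 rose in LysM-CRL early and 13 in granulocyte progenitor-like cells (4 and 6 of these calls ended with a library left out), in libraries that also held more mature neutrophil-like cells. In granulocyte progenitor-like cells these and the granule genes that rose kept 87.2% of their median log2 change with clusters matched in cell number (1.56 before and 1.36 after), which argues against cluster makeup. The gain in UMIs per cell was 2.62 and 2.03 times that in lymphoid-like cells (median of 19 genes; 18 and 15 above 1, exact sign test p = 7.63e-05 and 0.0192, genes not being independent), but in LysM-CRL 2 it was 5.20 times that in NK cell-like and only 1.26 times that in B cell-like cells (11 above 1, exact sign test p = 0.648). In early progenitor-like cells the ratios were 1.91 and 0.983, with 2.63 against NK cell-like and 0.656 against B cell-like cells of LysM-CRL 2 (5 above 1, exact sign test p = 0.0636). Free RNA can therefore not be told apart from expression in either class, and doublets below the score threshold, maturation within a cluster and an effect of the genotype stay open and untested.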

How the results depend on the processing

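The settings with all libraries clustered together and with clusters drawn in equal number were chosen only after the data were seen, as was the comparison of both mutants' changes under settings other than a left-out library, clustering and thinning, and for single genes the stricter cell filter, doublets kept, thinning and the other clusterings. With 2 libraries per genotype, each left-out library leaves a group of 1, whose spread is assumed to equal that of the others. Of 133 calls of named genes and list members for LysM-CRL against WT, 61 held in every setting planned for single genes (DESeq2, RLE factors, no filter, replicate block, 2 groups and left-out libraries) and 72 ended in 1 or more, while all 86 and 48 calls of LysM-CRS against WT and LysM-CRL held in them. In the settings added later, 46, 7 and 0 of these calls ended with each library clustered alone (24, 18 and 10 could not be tested there), 25 of the first with matched clusters (2 not tested), 19, 1 and 1 with all libraries together, 17, 0 and 0 thinned (3, 0 and 1 not tested), 8, 1 and 0 with the stricter cell filter, 9, 0 and 0 with doublets kept and 10, 0 and 0 at a resolution of 0.5. None of them changed sign where tested. Monocyte-like cells of WT, 169 and 133 in number, and the lower depth of LysM-CRS set the limits. Each library clustered alone gave no monocyte-like value because WT 1 then held no such cluster. The cause of the changes below was not tested, except where a setting tests more genes or fewer cells or libraries by construction.

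Counts of genes changed in LysM-CRL against WT moved most, from 56, 346, 2282, 248 and 313 in early progenitor-like, granulocyte progenitor-like, immature neutrophil-like, mature neutrophil-like and monocyte-like cells. Leaving out 1 library gave ranges, in that order, of 15 (without WT 1) to 189 (without LysM-CRL 2), 115 (without WT 1) to 480 (without LysM-CRS 1), 275 (without WT 1) to 3942 (without LysM-CRS 1), 65 (without WT 2) to 337 (without LysM-CRS 2) and 40 (without LysM-CRL 1) to 1010 (without LysM-CRS 2). Early progenitor-like cells had 200 with DESeq2, 94 with the stricter cell filter, 86 with doublets kept, 496 with matched clusters, 726 with no filter on low counts, 17 with all libraries clustered together and 0 with each library clustered alone (455 at an unadjusted p under 0.05 in edgeR, DESeq2 not run there). Granulocyte progenitor-like cells had 166 with all libraries together, 202 with doublets kept, 4 with each library alone, 649 with no filter and 158 at a resolution of 0.5. Immature neutrophil-like cells had 1158 with matched clusters, 4009 with only the 2 groups fitted and 1336 thinned to the smallest library. Mature neutrophil-like cells had 605 with each library alone, 377 with matched clusters and 912 with no filter. Monocyte-like cells had 509 with doublets kept, 139 with matched clusters, 880 with no filter, 1009 with only the 2 groups fitted, 2819 at a resolution of 0.5 and 206 thinned. With each library clustered alone LysM-CRS differed from WT at 846 and 4418 and from LysM-CRL at 692 and 4621 genes in early and granulocyte progenitor-like cells, down from 7945, 8391, 7698 and 8367. The count of monocyte-like genes between the mutants ran from 1728 (without LysM-CRL 2) to 3593 (without LysM-CRS 2), below the 3625 of all libraries.

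Replicate numbers do not pair the libraries: over the 5 classes, same-numbered deviations from the group means correlated at -0.228 to 0.207, with only 2 pairs, and no crossed pairing was tried. The replicate block gave 1419 genes in LysM-CRL immature neutrophil-like cells against 2282, moved no other count of genes by over 1.5 times and ended 8 calls of named genes.

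Gene lists passed in 56, 21 and 25 of 129 tests for LysM-CRL against WT, LysM-CRS against WT and LysM-CRS against LysM-CRL. With an estimated correlation camera gave 0, 0 and 0, with 5, 2 and 2 at an unadjusted p under 0.05. For the latter pair of comparisons there were 37 and 42 with no filter and 12 and 15 with each library clustered alone. The share of mature neutrophil-like cells in the neutrophil series was higher in LysM-CRL than WT by 30.1 percentage points, and by 22.3 with each library alone and 23.7 with all together. In LysM-CRS it was higher than WT by 20, and by 26.1, 33.4, 31.3 and 24.5 with each library alone, all together, the stricter cell filter and doublets kept. LysM-CRS minus LysM-CRL was -10.1 and turned to 3.89, 9.71 and 2.37 in the first 3 of these, or -5.86 with doublets kept. Of all cells the mature neutrophil-like difference turned from -13.0 to 1.33 with all libraries together.

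The correlation of both mutants' changes was 0.130 in granulocyte progenitor-like cells, and 0.261 with all libraries together, 0.268 with each alone, 0.235 with no filter, 0.0525 with the stricter cell filter, 0.244 at a resolution of 0.5 and 0.0338 (without LysM-CRL 1) to 0.209 (without WT 1). In monocyte-like cells it was 0.481, and 0.424 with doublets kept, 0.539 with no filter, 0.558 with only the 2 groups fitted, 0.372 at a resolution of 0.5 and 0.479 (without LysM-CRS 1) to 0.580 (without WT 1). It was 0.276 and 0.456 in immature and mature neutrophil-like cells with no filter, against 0.222 and 0.253, the latter ranging over 0.256 (without LysM-CRL 1) to 0.420 (without WT 2). Targeted genes changed sign only where their log2 change had not passed the test. Cpsf6 in LysM-CRL early progenitor-like cells was at -0.072, -0.0038 and -0.013 with matched clusters, no filter and the 2 groups. Hdac3 was at -0.0046 in LysM-CRL early progenitor-like and -0.040 in LysM-CRS granulocyte progenitor-like cells against WT with all libraries together. In LysM-CRS against LysM-CRL, Rarg in early progenitor-like cells was at 0.0044 with DESeq2 and 0.0096 with RLE factors. With all libraries together it was at -0.35, -0.43 and -0.35 in granulocyte progenitor-like, immature and mature neutrophil-like cells, Lyz2 at 0.060 in immature neutrophil-like cells, and Rarg in mature neutrophil-like cells at -0.18 with no filter and -0.038 with the 2 groups. Tgm2 in LysM-CRL immature neutrophil-like cells was at -0.18 with matched clusters. With 1 library left out, LysM-CRL against WT had Cpsf6 at -0.044 to 0.052 in early and -0.073 to 0.030 in granulocyte progenitor-like cells, and Hdac3 at -0.077 to 0.13, -0.059 to 0.25 and -0.033 to 0.67 in these and monocyte-like cells. LysM-CRS against WT had Hdac3 at -0.088 to 0.21 and Rarg at -0.45 to 0.042 in granulocyte progenitor-like and Lyz2 at -0.65 to 0.33 in monocyte-like cells. Between the mutants Hdac3 was at -0.082 to 0.012 in granulocyte progenitor-like cells and Rarg at -0.37 to 0.49, -0.16 to 0.33, -0.12 to 0.35, -0.10 to 0.13 and -0.37 to 0.036 in the 5 classes, in the order given above.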

Other observations

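Which of the lists and cell types to describe here was chosen after their results were seen. Single members of further gene groups changed in LysM-CRL immature neutrophil-like cells. Of 20 myeloid transcription factor genes, 3 rose (2 rose adjusted over the list alone; adjusted p = 0.279 in camera, adjusted p = 0.598 with an estimated correlation). Cebpa, the factor of granulocyte commitment, was at 0.87 ± 0.16, Cebpb at 0.76 ± 0.18 and Klf2 at 0.82 ± 0.23 (log2 change ± SE, n = 2 libraries per group, adjusted p = 0.0129, 0.0296 and 0.0486, edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Of 18 glycolysis genes, 3 rose (5 rose adjusted over the list alone; adjusted p = 0.0161 in camera, adjusted p = 0.598 with an estimated correlation). Pfkfb3 and Pfkp, enzymes around the phosphofructokinase step, and the glucose transporter gene Slc2a3 stood at 0.43, 0.58 and 0.47. Of 20 genes of the unfolded protein response, 3 rose and 1 fell (6 rose and 2 fell adjusted over the list alone; adjusted p = 0.0843 in camera, adjusted p = 0.714 with an estimated correlation). Xbp1, its transcription factor, was at 0.37, and the chaperone genes Canx and Hspa5 at 0.30 and 0.52, against Herpud1 at -1.15. Of 13 genes of retinoid receptors and corepressors, 3 rose (4 rose and 1 fell adjusted over the list alone; adjusted p = 0.228 in camera, adjusted p = 0.598 with an estimated correlation). Rara stood at 0.77, Ncor1 at 0.30 and Hdac2 at -0.36. Of 8 erythroid marker genes, 4 fell (5 fell adjusted over the list alone; adjusted p = 0.0141 in camera, adjusted p = 0.598 with an estimated correlation), with Car1 at -1.87, and of 9 B cell marker genes, 3 fell (4 fell adjusted over the list alone; adjusted p = 0.0995 in camera, adjusted p = 0.698 with an estimated correlation), with Cd79b at -1.16, in libraries that held fewer erythroid-like and B cell-like cells. Each of the calls named here except Herpud1 ended without WT 1 (adjusted p = 0.0508 to 0.189, edgeR quasi-likelihood test, Benjamini-Hochberg adjustment) and without WT 2 (adjusted p = 0.0663 to 0.222), and Hdac2 did not pass (adjusted p = 0.0511). With matched clusters 3 of 3 myeloid factor, 1 of 3 glycolysis, 0 of 4 unfolded protein, 2 of 3 receptor, 2 of 4 erythroid and 1 of 3 B cell marker calls ended. Among these lists, the glycolysis call ended without LysM-CRL 1 (adjusted p = 0.0712 in camera) and with matched clusters (adjusted p = 0.0790), and the erythroid call without WT 2 or with matched clusters (adjusted p = 0.0527 in each).

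In LysM-CRL monocyte-like cells, of 21 monocyte and macrophage genes, 6 rose and 2 fell (8 rose and 4 fell adjusted over the list alone; adjusted p = 0.0908 in camera, adjusted p = 0.703 with an estimated correlation). Treml4 and Ace, genes of nonclassical monocytes, stood at -2.10 and -1.94 and Cd14 at 1.60. Of 16 genes of p53 and cell death, 3 fell (1 rose and 4 fell adjusted over the list alone; adjusted p = 0.167 in camera, adjusted p = 0.703 with an estimated correlation). Beside Bcl2, the survival genes Bcl2a1d and Bcl2a1b, near-identical copies and so uncertain, stood at -2.23 and -2.20. Of the 8 monocyte and macrophage calls, 2, 6, 5 and 5 ended without WT 1, WT 2, LysM-CRL 1 and LysM-CRL 2, and 6 with matched clusters, where Treml4 stood at -0.73 and Ace at -0.48, whereas the 3 survival calls held in each of these.

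The names of rare cell types depended on clustering. T cell-like cells numbered 179 in LysM-CRL 1, 2 in LysM-CRL 2, 1 in WT 2 and 0 in WT 1, but with each library clustered alone 2.06% of LysM-CRL 1 and 2.23% of WT 2 took the name, and no cell of WT 2 was then named NK cell-like. The FLAG-CRL-tdtomato feature, counted in the LysM-CRS files alone, had 3 and 0 UMIs there, the latter allowing a share of cells of up to 0.0347%. Xist, which marks female cells, passed the low-count filter in none of the 5 classes, and Ddx3y, a Y-linked gene, stood at 32.8 and 30 CPM in WT, 50.1 and 52.8 in LysM-CRL and 16.2 and 14.6 in LysM-CRS immature neutrophil-like cells.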
